A study of Mus musculus with 4 samples.

How the data were processed

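The series holds 4 microarray libraries of BA/F3 cells, an established mouse line that depends on interleukin 3 and is widely used as a model of early B cells. By title, source name and genotype, 2 libraries come from cells that carry an inducible human ETV6-RUNX1 (TEL-AML1) fusion gene and 2 come from control cells. ETV6-RUNX1 is the fusion transcription factor made by a translocation common in childhood B-cell leukemia. Per the labels' protocols, both lines received mifepristone, the inducer, at 32.5 pM for 16 h, and total RNA was extracted. The RNA was labelled with biotin by a 3' in vitro transcription kit.

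The labels disagree on 2 points. The free-text description field calls the library titled ETV6-RUNX1 replicate 1 a control, and it calls the library titled control replicate 1 a fusion-expressing library; for both replicate 2 libraries it names the same condition as the title. The series design text speaks of chromatin immunoprecipitation over promoters and the titles carry the same term, whereas the protocols describe total RNA, and the table holds 1 value per probe set of a mouse 3' expression array. The values were therefore treated as RNA levels, and no promoter binding was analysed here.

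The deposited table gives log2 values for 45101 probe sets, which the authors made with GCRMA 2.28.0, per the submitters' processing notes. GCRMA corrects background with probe sequence, normalizes and summarises each probe set. That the scale is log2 was read from the values, which run from 2.23 to 16.3 with the same lowest value in every library. Filters, batch steps and the test used by the authors are not given in the sources used here. Each library's median lay between 2.35 and 2.36, because 54.8% to 55.0% of its probe sets lay within 0.5 of the lowest value. A value near that floor is a background level, so a difference from it is compressed and its size is not a measured fold. The summary step left 1056 tested probe sets, 5.96%, with identical values in at least 2 libraries. Scanner files, scan dates and batches were not used here. Arrays carry no read depth, and the number of libraries limits the precision.

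All 64 control probe sets were left out of the tests, and a probe set was tested when its mean over the 4 libraries was at least 4, which kept 17720. Probe sets were named from the platform annotation. On the whole array 34958 had 1 symbol, 932 had several and 9211 had none; the update of symbols through Entrez identifiers changed 0 names. Named genes came only from probe sets with 1 symbol. Where a gene had several tested probe sets, the one with the highest mean stood for it, which gave 8892 genes. Probe sets of 1 gene are told apart below by their mean level.

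Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Each fit used all 4 libraries, 2 per group, which leaves 2 residual degrees of freedom. Grouping by title was the main comparison, and grouping by the description field was fixed as its alternative before the data were examined, as were the gene lists, the naming rule and the other settings. Nothing in the labels says that same-numbered libraries came from 1 culture or day, and the replicates are called independent without saying how, so the p-values measure the spread between these libraries.

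In all, 23 gene lists with 554 genes were fixed, of which 505 genes had a named probe set on the array and 361 were tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it, all adjusted over the 22 lists with at least 2 tested genes. Of these, 1 is counted among the lists but not reported here. Members were also counted after adjustment over the list alone. The naming rule took first every probe set of Etv6, Runx1, Runx2, Runx3 and Cbfb. It then took the 12 most raised and the 12 most lowered genes past the threshold with non-overlapping groups. Where fewer than 5 passed, it took up to 10 per direction at an unadjusted p under 0.01, and these are said not to have passed. From each list up to 4 members with the smallest p could be named. Genes outside this rule are said to have been chosen after their values were seen. Genes known only by a predicted or clone name were skipped in the naming.

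The test was checked on simulated libraries made from the real probe set means and fitted spread, with 50 of the 17720 probe sets changed by each of 4 sizes. In the title comparison 2.0%, 12.0%, 76.0% and 96.0% of changes of 1, 2, 4 and 6 on the log2 scale were called, with 3 false calls. In the description comparison 4.0%, 64.0%, 94.0% and 100.0% were called, with 4 false calls. A list shifted by 1 was called in both, and 0 unshifted lists were. The simulated genes varied independently, so this check does not cover correlation between genes, on which the list calls below depend. Its noise was normal and drawn from the moderated spread, without a floor or ties, so the shares called may be too high for the real values. In the real description comparison the 10 raised genes named below differed by 4.63 to 6.46. None of them passed at the probe set that stands for the gene.

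The alternatives were a replicate block, the description grouping, no filter and a minimum mean of 6, median centring, a second quantile normalization, no variance trend, a robust fit, the mean over a gene's probe sets, other set tests and leaving out each library in turn. After the data were seen, a crossed block, the same alternatives for the description grouping, the difference within the replicate 2 pair and the split by replicate number were added.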

Results

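RNA levels were measured in 4 libraries of mifepristone-treated BA/F3 cells, 2 titled as carrying the inducible ETV6-RUNX1 fusion and 2 titled as control. The comparison asks how expression of the fusion changes transcript levels relative to control cells given the same inducer. In each library between 17517 and 17688 probe sets had a log2 value of 4 or more. Because the description field exchanges fusion and control for the 2 replicate 1 libraries, every comparison is given under both labels, and libraries are named by their titles.

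The libraries lay closest to each other in the pairs that the description field names. Over the 17720 tested probe sets, the library titled control replicate 1 correlated best with the library titled ETV6-RUNX1 replicate 2, at a Pearson r of 0.972. The library titled ETV6-RUNX1 replicate 1 correlated best with control replicate 2, at 0.966. The 2 libraries titled ETV6-RUNX1 correlated at 0.947 and the 2 titled control at 0.931, the lowest of the 6 pairs. These correlations are across probe sets, which are not independent replicates. Of the variance between the libraries, 53.9% lay along the description split, 36.5% between replicate 1 and replicate 2, and 9.61% along the title split.

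The fusion minus control difference, taken by title, ran in opposite directions in the 2 replicates. Across the tested probe sets the difference of replicate 1 correlated with that of replicate 2 at a Pearson r of -0.70 and a Spearman correlation of -0.66. Of the 2027 probe sets that differed at least 2-fold between the replicate 2 libraries, 1866, or 92.1%, had the opposite sign in replicate 1. The 2 differences share no library, but their opposition follows from the larger variance along the description split than along the title split.

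**Figure D1:**
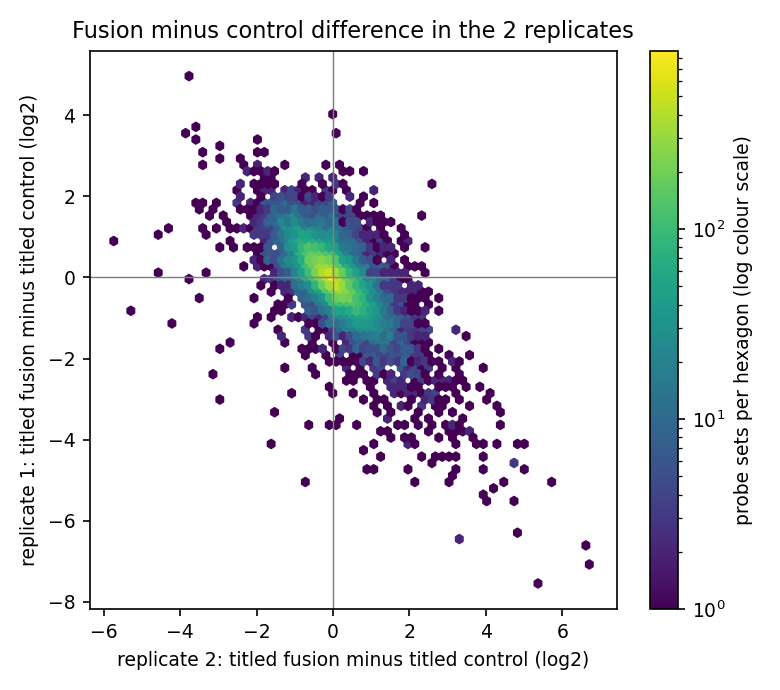
Each hexagon counts tested probe sets by their fusion minus control log2 difference, taken by title, in replicate 2 (horizontal axis) and replicate 1 (vertical axis), with a log colour scale. The cloud runs from the upper left to the lower right, with a Pearson r of -0.70.

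The probe sets of the fused genes themselves did not separate the libraries by title. All 6 probe sets of Runx1, which encodes a core hematopoietic transcription factor, were lower on average in the libraries titled ETV6-RUNX1, and all 6 were higher in the libraries described as fusion-expressing. Within the replicate 2 pair, where the labels agree, they differed by 0.58, 0.78, 0.18, 0, 0 and 0.0877, from the highest to the lowest mean level. The values of 0 come from tied readings, so the count of 6 rests largely on the replicate 1 pair. The one with the highest mean level read 8.24 ± 1.05 (SD, n = 2) by title in fusion and 8.57 ± 0.23 in control libraries, a log2 difference of -0.32 (SE 0.60). By description it read 8.86 ± 0.18 in fusion and 7.95 ± 0.64 in control libraries, a difference of 0.90 (SE 0.38, limma adjusted p = 0.31). The Runx1 probe set with the next highest level differed by -0.38 (SE 0.70) by title and by 1.16 (SE 0.36, adjusted p = 0.22) by description.

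Etv6, which encodes a transcriptional repressor, was measured by 2 probe sets. The brighter differed by -0.12 (SE 0.30) by title and by 0.35 (SE 0.18) by description. Runx3, a paralogue of Runx1, differed at its tested probe set by 0.65 (SE 0.80) by title and by -1.48 (SE 0.37, adjusted p = 0.18) by description. Its other probe set lay below the filter, at 3.87 in the library titled ETV6-RUNX1 replicate 1 and 3.28 in the library titled ETV6-RUNX1 replicate 2. Cbfb, the shared partner subunit of RUNX proteins, differed by -0.21 (SE 0.15) by title and by -0.01 (SE 0.14) by description. None of these differences passed the threshold in either grouping. The transgene is human and the probe sets are mouse, so whether they detect the fusion transcript is not known. Runx2 was not analysed here.

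**Figure D2:**
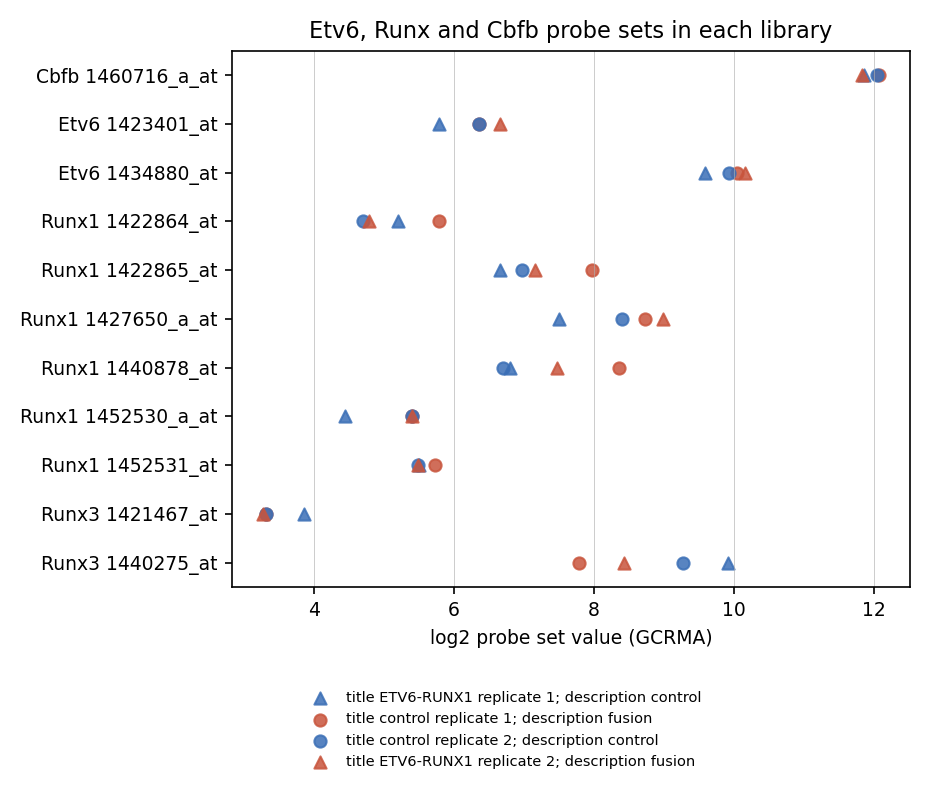
Log2 values of the Etv6, Runx1, Runx3 and Cbfb probe sets in each library, with the title as the symbol's shape and the description as its colour. At the Runx1 probe set with the largest difference the 2 libraries described as fusion-expressing average 7.92 and the 2 described as control 6.75.

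Grouped by title, no probe set passed the threshold between fusion and control libraries. Of 17720 probe sets, 0 passed an adjusted p of 0.05 in limma, the lowest adjusted p was 1, and 50 had an unadjusted p under 0.05, where chance alone would give 886. The rule for named genes left 0 genes in either direction. At least 2-fold differences without overlap occurred in 76 probe sets, 42 higher and 34 lower in the libraries titled fusion. Groups of 2 failed to overlap at 10.7% of probe sets, against 33.3% by chance. A probe set without ties fails to overlap in only 1 of the 3 ways to split 4 libraries. The low share here and the high share by description are therefore not separate results. The description difference also counts as spread within the title groups, which lowers the number of small p-values.

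Among the fixed lists, 2 of 22 fell by title at the preset correlation. Immediate early genes, which encode rapidly induced regulators, were lower in 10 of 11 tested members, with a median of -0.54 (camera adjusted p = 2.3e-05, and adjusted p = 0.86 with an estimated correlation). Fos differed by -0.99 (SE 0.38), Btg2 by -0.65 (SE 0.36), Dusp1 by -0.58 (SE 0.28) and Klf6 by -0.54 (SE 0.37). Markers of myeloid cells, mast cells and basophils were lower in 11 of 12 members, with a median of -0.86 (camera adjusted p = 0.00035, and adjusted p = 0.86 with an estimated correlation). Ms4a2, the IgE receptor beta chain, differed by -1.46 (SE 1.21) and Gata2 by -0.35 (SE 0.29). No member of either list passed, whether adjusted over all probe sets or over the list alone. The immediate early list had a median of -1.04 in replicate 1 and only -0.15 in replicate 2. The 2 replicates did not give the second list the same direction, since its median was -2.18 in replicate 1 and 0.40 in replicate 2. Without the library titled ETV6-RUNX1 replicate 1 the adjusted p became 0.45 and 0.90, and without the library titled control replicate 1 it became 0.087 and 0.48. Without the library titled control replicate 2 the immediate early list had 0.12 and the marker list 0.040, and without the filter they had 0.072 and 0.048. The other 20 lists had adjusted p-values of 0.12 to 0.95.

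Grouped by the description field, the libraries called fusion-expressing had high values for a set of genes that lay at the floor in the others. Among these was Gtsf1, which encodes a germline small-RNA pathway protein. One of its probe sets read 9.28 ± 0.13 (SD, n = 2) against 2.33 ± 0.08, a log2 difference of 6.95 (SE 0.18, limma adjusted p = 0.047). A probe set without a symbol read 8.92 ± 0.03 against 2.25 ± 0.00, a difference of 6.67 (adjusted p = 0.047). These 2 were the only probe sets past the threshold, both higher, and were singled out after their values were seen. At an adjusted p under 0.1 there were 12. Both calls had control-described values near the floor, and the unnamed probe set read the same value in both of those libraries. Spread is cut off at the floor, so the SE and p-value of both calls may be too small. The same holds for genes named below with values at the floor, such as Anxa3 and Slc9b1. At an unadjusted p under 0.05 there were 3494, 1874 higher and 1620 lower, against 886 by chance. At least 2-fold differences without overlap occurred in 1635 probe sets, 977 higher and 658 lower, and groups failed to overlap at 50.4% of probe sets against 33.3% by chance. The 2 calls were lost with any 1 library left out, with lowest adjusted p-values of 0.345 to 0.481, and without the filter, with 0.101.

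The naming rule took 10 genes with higher and 10 with lower values in the libraries described as fusion-expressing. None of the 20 genes named here passed the threshold at the probe set that stands for the gene, with adjusted p-values of 0.056 to 0.16. Fcer1a, the high-affinity IgE receptor alpha chain, read 8.80 ± 1.57 (SD, n = 2) in the libraries described as fusion-expressing and 2.35 ± 0.03 in those described as control, a difference of 6.46 (SE 0.82). The Gtsf1 probe set with the higher mean level differed by 5.58 (SE 0.43), Anxa3, an annexin, by 5.17 (SE 0.36), and Gsta3, a glutathione transferase, by 4.90 (SE 0.99). Lgals3, which encodes galectin-3, was higher by 4.80 (SE 0.19) and Slfn4 by 4.78 (SE 0.70). Slc11a1, a phagosomal metal transporter, was higher by 4.74 (SE 0.43) and the chemokine receptor gene Ccr2 by 4.68 (SE 0.44). Hal, histidine ammonia-lyase, differed by 4.74 (SE 0.21) and Slc9b1, a sodium/proton exchanger, by 4.63 (SE 0.18).

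Of the 10 named genes with lower values in the libraries described as fusion-expressing, Parp8 differed by -4.39 (SE 0.34) and Bend5 by -3.52 (SE 0.21). Mt2, a metallothionein, read 7.76 ± 0.24 (SD, n = 2) against 11.41 ± 0.21, a difference of -3.66 (SE 0.21). Myc, the proto-oncogene for a growth-promoting transcription factor, read 7.61 ± 0.48 against 10.16 ± 0.30, which is 5.84-fold lower (log2 difference -2.55, SE 0.33, limma adjusted p = 0.13). Idh2, a mitochondrial isocitrate dehydrogenase, differed by -3.08 (SE 0.63) and Padi4, a peptidylarginine deiminase, by -3.21 (SE 0.59). The other named genes were Ccnb1ip1 at -3.11, Ttc25 at -2.62, Ceacam1 at -2.53 and Map7d1 at -2.50.

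**Figure D3:**
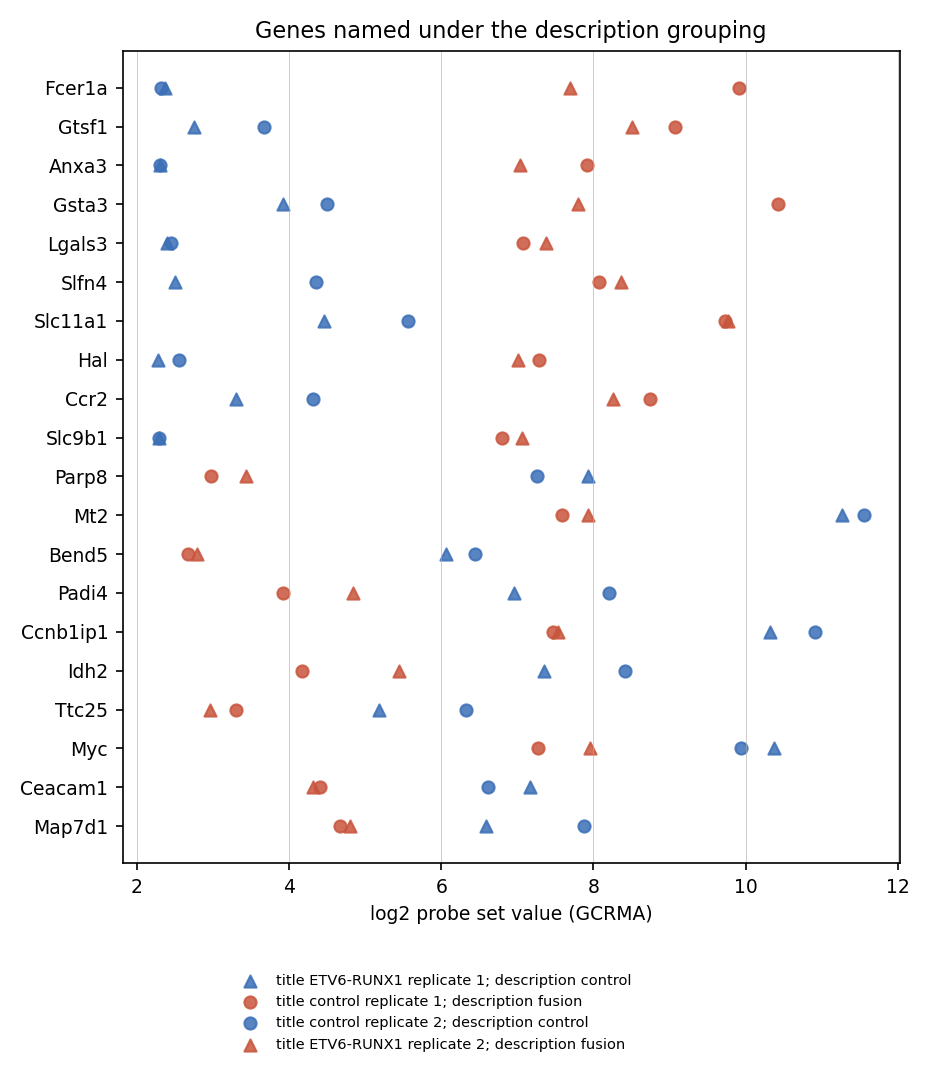
Log2 values of the 20 genes named under the description grouping in each library, with the title as the symbol's shape and the description as its colour. The 2 colours separate for every gene because the naming rule required it, as for Mt2 with 7.76 against 11.41 by description.

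By description, the list of MYC, ribosome biogenesis and nucleolar genes fell. All 25 tested members were lower, with a median of -1.26 (camera adjusted p = 2.8e-12, and adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone 19 members passed, and over all probe sets tested 0 did. Myc is itself a member. Npm1, which encodes nucleophosmin, differed by -0.55 (SE 0.07), Dkc1, the pseudouridine synthase dyskerin, by -1.21 (SE 0.14) and Mybbp1a, a nucleolar protein, by -1.58 (SE 0.26). Within the replicate 2 pair, which is part of the description grouping and so no separate check, the list's median was -1.04. It lay below all of 10000 random lists matched on mean expression and drawn gene by gene. In the same libraries the markers of myeloid cells, mast cells and basophils had a median difference of 1.22. The dap labelling spike, a transcript added before labelling, had a 3' minus 5' difference that was larger there by 0.93 and 0.85 at its 2 probe set pairs, beyond the 0.72 and 0.31 within the description pairs. That of the lys spike was larger by 0.0908 at 1 pair, beyond the 0.0317 within the description pairs, and by 0.14 at the other, under the 0.16 within them. At the thr spike the 3' probe sets differed by 0.25 at both pairs and the dim 5' probe sets by -0.0748 and -0.34. Its 3' minus 5' difference was thus larger there at both pairs, beyond that within the description pairs.

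RUNX1 and ETV6-RUNX1 target genes taken from the literature rose as a list, with 15 of 20 higher and a median of 0.28 (camera adjusted p = 0.027, and adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone 3 passed, all higher, and over all probe sets 0 did. These were Bcl6, a transcriptional repressor of germinal centre B cells, at 4.48 (SE 0.28), Tal1, a hematopoietic transcription factor, at 1.39 (SE 0.15) and Ccnd3, cyclin D3, at 1.08 (SE 0.15). The call was lost without the library titled control replicate 1 (adjusted p = 0.057) and without the library titled ETV6-RUNX1 replicate 1 (adjusted p = 0.12).

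The p53 target and apoptosis list rose, with 20 of 26 members higher and a median of 0.46 (camera adjusted p = 0.027). Zmat3, a p53-induced RNA-binding protein, differed by 1.26 (SE 0.14) and was the 1 member that passed over the list alone, while 0 passed over all probe sets. Cholesterol and fatty acid synthesis genes fell, with 15 of 20 lower and a median of -0.26 (camera adjusted p = 0.027). Fdps, farnesyl diphosphate synthase, differed by -2.21 (SE 0.26) and was the 1 member past the threshold over the list alone. Heat shock genes fell in 6 of 7 members, with a median of -0.41 (camera adjusted p = 0.027), and Hspd1 differed by -1.56 (SE 0.44). No heat shock gene passed over the list alone. Each of these 3 lists had an adjusted p = 0.72 with an estimated correlation. Without the library titled control replicate 1 they had 0.10, 0.10 and 0.053, in the order given. Without the library titled ETV6-RUNX1 replicate 1 the p53 list had 0.053 and the heat shock list 0.0504, and without the library titled control replicate 2 the cholesterol list had 0.17. The heat shock list had 0.17 without the filter.

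The other lists did not pass by description. Markers of myeloid cells, mast cells and basophils had a median of 1.22 with 9 of 12 higher (camera adjusted p = 0.12). It passed without the library titled control replicate 2 (adjusted p = 0.0025) and without the library titled ETV6-RUNX1 replicate 2 (adjusted p = 0.024). Fcer1a and Hdc passed over the list alone, with Hdc, histidine decarboxylase, higher by 3.60 (SE 0.55). NF-kB response genes had a median of 0.49 (adjusted p = 0.22), and 4 of 6 passed over the list alone. Among these, Icam1 was higher by 1.26 (SE 0.20), Nfkbia by 0.90 (SE 0.15), Birc3 by 0.82 (SE 0.20), and Il6 differed by -0.83 (SE 0.21). Interferon response genes had a median of 0.42 (adjusted p = 0.074) and early B cell genes 0.40 (adjusted p = 0.22), with 0 members past the threshold over either list. IL-3, JAK and STAT5 signalling genes had a median of 0.18 (adjusted p = 0.38). Of its 25 members 3 passed over the list alone, Bcl6, Myc and Socs3, the last a feedback inhibitor of cytokine signalling at 1.72 (SE 0.18).

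Cell cycle genes had a median of 0.08 (adjusted p = 0.33) and 2 of 33 passed over the list alone, E2f2 at 2.00 (SE 0.20) and Ccnd3. DNA replication and repair genes had a median of 0.06 (adjusted p = 0.55) with 0 of 32 past the threshold. Cytosolic ribosomal protein genes had a median of -0.05 (adjusted p = 0.11) and oxidative phosphorylation genes -0.03 (adjusted p = 0.67), with 0 members past the threshold over either list. The integrated stress and unfolded protein response list had a median of -0.27 (adjusted p = 0.23) and immediate early genes 0.25 (adjusted p = 0.38), with 1 member each past the threshold over the list alone, Edem1 at 0.98 (SE 0.13) and Ier5 at 1.15 (SE 0.17). Glycolysis and hypoxia genes had a median of -0.04 and a mean of 0.21 (adjusted p = 0.86), and Ddit4 and Ero1a passed over the list alone. Histone and chromatin genes had a median of 0.08 and a mean of -0.09 (adjusted p = 0.86), and Hdac1, H1f2 and Dnmt3a passed over the list alone. Megakaryocyte and erythroid markers had a median of 0.10 and a mean of -0.24 (adjusted p = 0.74). The ETV6, RUNX and partner list had a median of 0.11 (adjusted p = 0.70), and the 2 tested fibroblast and stromal markers, Acta2 and Vim, 0.79 (adjusted p = 0.22), with Acta2 past the threshold over the list alone.

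**Figure D4:**
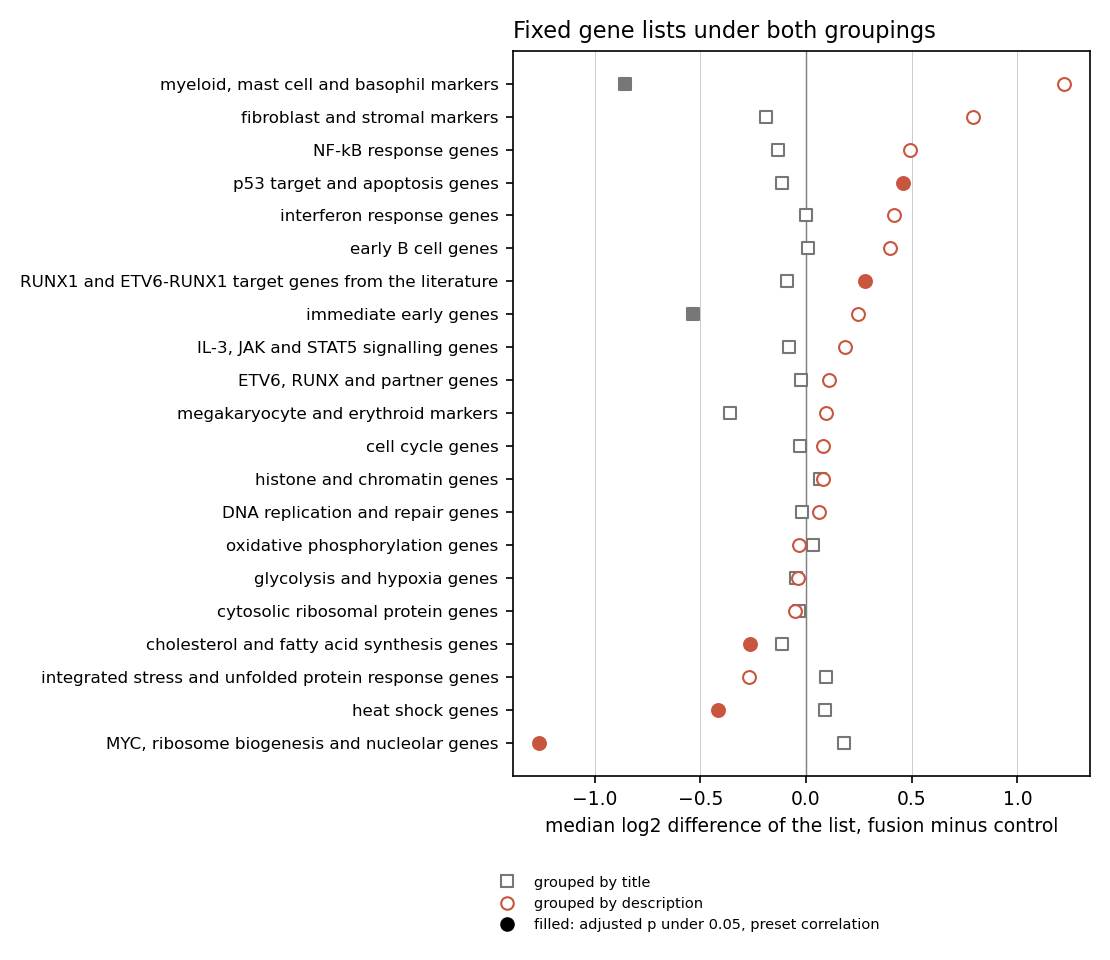
Median log2 difference, fusion minus control, of each reported gene list under the title grouping (squares) and the description grouping (circles), filled where camera's adjusted p at the preset correlation is under 0.05. The MYC, ribosome biogenesis and nucleolar list lies at -1.26 by description, and no list is filled at an estimated correlation.

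The library titled ETV6-RUNX1 replicate 2 and the library titled control replicate 2 are the only pair for which all labels agree, and with 1 library each the difference has no replicate check. Between them 1195 probe sets were at least 2-fold higher and 832 at least 2-fold lower in the fusion library. Bcl6 differed by 4.84, Fcer1a by 5.37, Fdps by -2.57 and Myc by -1.99. Both libraries also enter the description grouping from which these genes come. The same direction here, also of the lists below, is therefore no separate check. The matched random lists were drawn gene by gene and do not keep the correlation between list members. Medians of the p53 target and apoptosis list (0.37) and of the interferon list (0.69) lay above 99.9% of matched random lists. The median of the cholesterol and fatty acid synthesis list (-0.34) lay above 0.48% of them, and that of the heat shock list (-0.52) above 0.20%.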

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

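Tests of exchanged titles, RNA degradation, hybridisation, a cell line difference and ribosomal RNA were chosen after the result was seen; those of paired probe sets and of a single library were set before their results.

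The transferrin receptor control probe sets, which entered no comparison, stood apart in the library titled ETV6-RUNX1 replicate 1. The 5' probe set read 6.29 there and at most 2.89 in the control-titled libraries, a log2 excess of 3.40, and the middle probe set read 5.16 against 3.55, an excess of 1.62. The 3' probe set read 7.60 there and 7.29 in the library titled ETV6-RUNX1 replicate 2. Tested probe sets of the gene, Tfrc, read 13.56 there against 12.43 to 12.89 in the others at the brightest, 7.74 against 6.77 to 7.55 at the next and 6.75 against 3.22 to 3.56 at the last.

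The first pattern is that the libraries group by description and not by title. An exchange of the titles, source names and genotypes of the 2 replicate 1 libraries would make the replicate differences oppose each other. Their correlation was -0.70 (95% bootstrap interval over probe sets -0.71 to -0.68). That value follows from the larger variance along the description split than along the title split. It restates the pattern and cannot decide on its cause, so an exchange stays open. Hybridisation is argued against, since 18 spike probe sets differed by a median of 0.0864 and a range of -0.09 to 0.16. RNA degradation and labelling length were tested together. The 3' minus 5' difference of beta-actin differed between the description pairs by only -0.0295 and that of Gapdh by 0.0237, less than within a pair. For these transcripts that argues against degradation of the cell RNA. Labelling length stays open. The dap spike, which was added before labelling and so does not measure degradation in the cells, differed by 0.93 and 0.85, more than within a pair. The lys spike differed at 1 of its 2 probe set pairs by 0.0908, more than within a pair. Its other pair differed by 0.14 and the phe pairs by 0.0398 and -0.0785, less than within a pair. The thr spike was left out of that test. Its 3' probe sets differed by 0.25 at both pairs and its dim 5' probe sets by -0.0748 and -0.34, in the same direction as dap. At both pairs its 3' minus 5' difference thus differed between the description pairs by more than within a pair. If the description labels are right, each description group is 1 line. A lasting difference between the 2 cell lines other than the fusion then cannot be told apart from the fusion. If the titles are right, each description group holds both lines, and a line difference would run along the title split instead. In all, 12 probe sets lay within 0.5 of the floor in 1 description pair and at 6 or more in the other. The title and replicate splits had 0. The 3 ways to split 4 libraries are too few for a share under 0.05.

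The second pattern is a difference between replicate 1 and replicate 2, where 1392 probe sets had an unadjusted p under 0.05 and 0 passed adjustment in limma, with a lowest adjusted p of 0.28. If preparation acted on single probe sets, probe sets of 1 gene need not move together. Of 104 genes whose brightest probe set differed at least 2-fold between the replicate numbers, 80.8% (exact 95% interval 71.9% to 87.8%) had a second probe set moving the same way. Between the description pairs the share was 99.4% of 322 genes (97.8% to 99.9%). The second probe set moved 0.45 times as far as the first between the replicate numbers and 0.92 times between the description pairs. These 2 sets of genes were not matched on size of change. Differences over all tested probe sets had an SD of 0.67 by description and 0.55 by replicate number. That alone could lower the share and the distance between the replicate numbers. All 3 probe sets of 18S ribosomal RNA were higher in both replicate 1 libraries, by 1.36 on average, which fits a difference in RNA preparation; a difference between cultures also stays open, as most second probe sets did follow the first.

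The third pattern is the lower level of the immediate early and the mast cell lists in libraries titled fusion. The calls might rest on the library titled ETV6-RUNX1 replicate 1 alone, since without it the higher of the 2 adjusted p-values was 0.90. Both were also lost without the library titled control replicate 1 (0.087 and 0.48), and the immediate early list without the library titled control replicate 2 (0.12), so that list's call needed 3 of the 4 libraries. For the marker list, which had 0.040 without control replicate 2, a dependence on the single library cannot be told apart from a dependence on the replicate 1 pair.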

How the results depend on the processing

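The crossed block and all alternatives of the description grouping were added after the data were seen. By title, 0 probe sets passed under every alternative but the description grouping, which gave 2, both at least 2-fold. At an unadjusted p under 0.05 the 50 became 48 with the replicate block, 185 without the filter, 31 at a minimum mean of 6 and 123 to 448 with a library left out. The 2 lists called by title became 6 by description, with 0 shared, 1 without the filter, 0 at an estimated correlation, 0 with fry and 0 to 8 with a library left out; the replicate block kept both. By description, the 2 probe sets past the threshold, both at least 2-fold, became 0 with the replicate block (lowest adjusted p 0.059), 0 without the filter, 10 with median centring, 14 with quantile normalization and 0 with any library left out. At a minimum mean of 6 there were again 2, with 0 shared. The 3494 at an unadjusted p under 0.05 became 5579 with the replicate block and 1764 to 2524 with a library left out. The 6 lists became 0 at an estimated correlation, 0 with fry (lowest adjusted p 0.13) and 2 to 8 with a library left out, where the MYC list was called each time; the replicate block kept all 6. In the labels same-numbered libraries share only a number. In the values their deviations from the group means correlated at -0.20 by title and at 0.59 by description. A crossed block, tried for the title grouping, called 0 probe sets and 5 lists. The cause of these shifts was not tested. By description the title difference reversed for Runx1 (0.90, 1.16, 0.74, 0.11, 0.47 and 0.34, from the highest to the lowest mean level), Etv6 (0.35 and 0.44) and Runx3 (-1.48). With a library left out, title differences that reversed ran from -1.07 to 0.42, -1.21 to 0.45, -0.24 to 0.00687 and -0.80 to 0.29 for the Runx1 probe sets given above as 0.90, 1.16, 0.11 and 0.34, from -0.40 to 0.17 and -0.57 to 0.31 for Etv6, and from -0.0917 to 1.39 for Runx3. By description they ran from -0.00687 to 0.24 and -0.16 to 0.84 for the Runx1 probe sets given as 0.11 and 0.34 and from -0.13 to 0.11 for Cbfb, which was 0.0430 with quantile normalization. None of these was a called difference. With a library left out, the lone library is assumed to vary like the pair. Values near the floor limit what a difference can show.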

Other observations

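The genes named here were chosen after their values were seen. Most genes of early B cell identity lay at background in all 4 libraries. Of 30 early B cell genes named on the array, 8 reached a mean of 4. The B lineage factors Ebf1 and Pax5 peaked at 2.24 and 2.29, close to the lowest value of 2.23, and so did Il7r, Rag1, Vpreb1 and Dntt, each at 2.23; a value at the floor does not show that a gene is absent. Cd79b, a B cell receptor component, read 8.31 to 8.81, Ikzf1 9.70 to 10.45 and Ptprc, the leukocyte antigen CD45, 12.55 to 13.40. Of 16 T cell and NK cell markers named on the array 0 were tested, and Bcl11b was the brightest at 3.23.

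Of 26 markers of myeloid cells, mast cells and basophils named on the array 12 reached a mean of 4, and of 15 megakaryocyte and erythroid markers 6 did. Kit, Mcpt4, Vwf and Alas2 peaked at 2.23, Pf4 at 2.29, Cpa3 at 3.73 and Mcpt8 at 4.31. Other members were well above background in the same libraries. Gata2, a progenitor and mast cell transcription factor, read 12.44 to 13.26, Fcer1g, the shared Fc receptor gamma chain, 11.04 to 11.82, Gata1 8.56 to 9.58 and Itga2b, platelet integrin alpha IIb, 9.08 to 10.53. Mpo, myeloperoxidase, overlapped between the groups under both labels. It read 8.0 in the library titled control replicate 2, 4.48 in the library titled ETV6-RUNX1 replicate 2 and under 3 in both replicate 1 libraries, at 2.34 and 2.86. Cma1, mast cell chymase, read 11.39 and 7.99 in the libraries described as fusion-expressing and 6.27 and 2.23, the floor, in those described as control. Its difference of 5.44 (SE 1.93, limma adjusted p = 0.26) did not pass the threshold. Klf1, an erythroid transcription factor, read 8.80 and 7.39 in the libraries described as control and 5.93 and 5.52 in those described as fusion-expressing, a difference of -2.37 (SE 0.56) that did not pass the threshold.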
